A study of Mus musculus with 6 samples.

How the data were processed

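RNA was measured by sequencing in 6 libraries, 3 from wild type and 3 from Girk3-null mice, 5 days old and of C57BL/6 background per the labels. Primary chondrocytes were freed from epiphyseal cartilage by collagenase digestion and washed, and total RNA was extracted, per the labels' protocols. Polyadenylated RNA was selected on oligo dT beads, made into TruSeq libraries and sequenced on an Illumina HiSeq instrument, per the labels' protocols. Samples were assigned to groups by the genotype label, and replicates were numbered in deposit order within a group, so a shared number pairs no samples. The series text calls the 3 libraries of a genotype biological replicates.

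The deposited table holds raw gene counts, 1 column per library, per the file headers. Reads were handled with bcl2fastq 2.19.0 and STAR 2.5.2b on genome build mm10, per the submitters' processing notes. The counting tool, the gene annotation, the strand setting and any filter are not given in the sources used here, so overlapping and antisense genes are treated as uncertain. The deposited table also holds RPKM values that the authors scaled by gene length and by library total, per the file headers and the labels' protocols. These RPKM equalled the count divided by the column total and by a length 1 base longer than the listed gene length. They were used only as an alternative unit, as log2(RPKM + 0.1) and log2(RPKM + 1) in limma. All 6 count columns and all 6 RPKM columns were matched to samples by the number in the sample title.

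The table lists 43346 genes, of which 15997 had 0 counts in every library. All 37 mitochondrial genes were at 0, so mitochondrial RNA could not be used to judge RNA quality. Total counts per library ranged from 34279516 to 60392837. A count of 0 allows up to 3 counts, which is 0.0497 to 0.0875 CPM (counts scaled to a fixed library total). Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates of a group differed far beyond sampling noise, with a chi-square per degree of freedom of 26.3 to 138 over genes with at least 20 counts, so no library was a copy of another in its group. Positions are those of the table, counted from 1. Of 42462 gene identifiers shared with GENCODE M21, 99.9% overlapped the same gene there.

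Differential expression was tested with edgeR 4.0.16 (quasi-likelihood F-test, model with genotype alone, TMM factors) in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 17554 genes holding 99.9% of the counts. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are TMM-scaled CPM as mean ± SD over 3 libraries, and standard errors are those of log2 fold changes. Log2 fold changes are Girk3-null over wild type, from the edgeR fit at its default prior count. Log2 CPM, used for the lists and principal components, had a prior count of 2. Their standard errors were derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. The biological coefficient of variation was 0.206. CPM in the check of sex-linked genes used the library totals alone.

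The main tests, the gene lists, the rule for naming genes and all alternatives but 2 were fixed before the data were examined. The 2 added after seeing the data were the unadjusted thresholds near Kcnj9 and leaving out genes of all other cell types, and later tests of explanations are named where they are given. The rule named Kcnj9, then up to 12 genes with the largest change per direction among those passing, with a mean log2 CPM of at least 1 and groups that did not overlap. Where fewer than 5 genes passed in a direction, the 8 with the smallest p-values in that direction at a mean log2 CPM of at least 1 were named as not passing. From each list up to 4 members with the smallest p-values were named, or 6 where more than 4 passed over all genes, which no list did. Of 31 lists, 29 were tested with limma 3.58.1. The GIRK channel subunits had 1 tested member, below the minimum of 3, and the list of male and X-inactivation genes served as a sample check. Of 611 distinct list genes, 604 were found by symbol and 4 by gene identifier, and 3 were not matched. Lists were tested with camera on log2 CPM with a preset correlation of 0.01. The estimated correlation and fry were run beside it. Whether genes near Kcnj9 were called more often was tested with Fisher's exact test, two-sided, in a window of 10 Mb.

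The edgeR and list tests were tested on simulated data made for the Girk3-null versus wild type comparison from the real means, library sizes and dispersions of 17554 genes, with 200 genes changed per run in 5 runs. The changed genes were drawn from those with a mean log2 CPM above 1. Among them the fit recovered 71.7% of 2-fold and 99.0% of 4-fold changes, and 5.78% of all calls were false. A list shifted by 0.5 on the log2 scale was called in 5 of 5 runs with the preset and in 3 of 5 with the estimated correlation. The simulated genes were independent of each other, unlike real genes, so recovery in the real libraries can be lower. In the real libraries 382 genes had an absolute log2 fold change of at least 1 and groups that did not overlap. Only 1 gene passed there, so the simulated shares do not give the recovery in the real libraries.

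Alternatives were DESeq2 1.42.0, limma-voom, relative log expression and upper-quartile factors, library size only, no low-count filter, at least 1 CPM in 3 libraries, RPKM, a covariate for sample title numbers below or above 200, other thresholds, and each library left out in turn. Genes of blood and muscle, and in an added alternative genes of all other cell types, were left out before scaling. With 3 libraries against 3 an exact permutation test cannot give a p below 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was excluded from the main comparison. Some genes that the naming rule or a test picked are not reported here by name.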

Results

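Polyadenylated RNA was sequenced from primary chondrocytes of the growing ends of bones of 5-day-old mice, released from cartilage by collagenase. The 6 libraries came from 3 wild type and 3 Girk3-null animals. Girk3 is a subunit of the G protein-gated inwardly rectifying potassium channels and is encoded by Kcnj9. The comparison asked which transcripts differ in chondrocytes that lack it. Total counts were 44291556, 50361885 and 42252651 in wild type replicates 1, 2 and 3, and 60392837, 44864868 and 34279516 in Girk3-null replicates 1, 2 and 3. Between 21892 and 23903 genes had at least 1 count in a library. Col2a1, the main collagen of cartilage, took 4.16%, 3.12% and 5.33% of all counts in the wild type libraries. Its share was 5.04%, 7.09% and 8.25% in the Girk3-null libraries.

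Kcnj9 itself (ENSMUSG00000038026; chromosome 1, 172320501 to 172329318, mm10) had 0 counts in all 6 libraries. A count of 0 allows up to 3 counts, or 0.0497 to 0.0875 CPM (counts scaled to the library total) depending on the library. The deleted transcript was therefore not counted in the wild type libraries either, and it could not be used to check the genotype labels. Whether it was absent or lost in counting is not known, since the counting tool is not given and all 37 mitochondrial genes were at 0 as well. The other subunit genes of these channels were close to that limit. Kcnj3 had 3 counts in wild type replicate 1 and 0 elsewhere, Kcnj6 had 0 to 3 counts, and Kcnj5 had 3 to 25. Kcnj5 was the only subunit gene with enough counts to be tested, at 0.363 ± 0.245 CPM in Girk3-null and 0.308 ± 0.128 CPM in wild type libraries (mean ± SD, n = 3 each).

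The sex label of 5 libraries did not match their transcripts. The labels give all 6 animals as male, but the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 16088 counts in Girk3-null replicate 1, 0 in each wild type library, and 1 and 7 in Girk3-null replicates 2 and 3. Xist, the RNA that coats the inactive X chromosome of females, had 19 counts in Girk3-null replicate 1 and 67346 to 144825 in the other 5. The number of genes called, Car8 and the gene lists that passed are therefore given below also without Girk3-null replicate 1. That leaves 5 libraries of the same pattern. Most other named genes and the genes near Kcnj9 were compared below with all 6 libraries only.

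**Figure D1:**
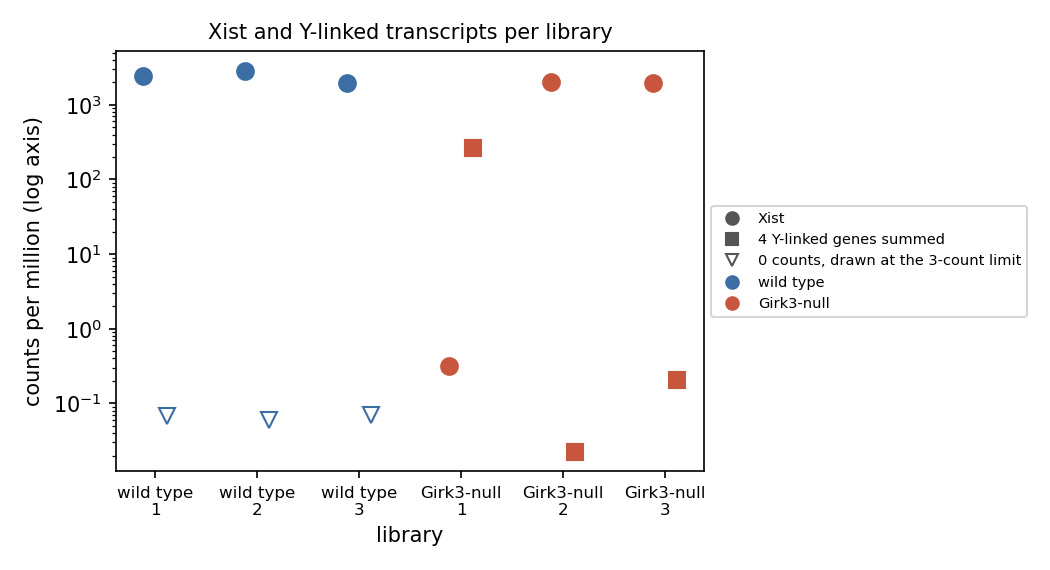
CPM (log axis) of Xist and of the sum of 4 Y-linked genes in each library, with open triangles for 0 counts drawn at the limit of 3 counts. Girk3-null replicate 1 has 266 CPM of Y-linked transcripts and 0.315 CPM of Xist, and the other 5 libraries have 1960 to 2876 CPM of Xist.

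Car8, which encodes a carbonic anhydrase-related protein (ENSMUSG00000041261; chromosome 4, 8143362 to 8239041, mm10), rose in Girk3-null chondrocytes. It measured 10.7 ± 0.362 CPM in Girk3-null and 3.28 ± 0.253 CPM in wild type libraries (mean ± SD, n = 3 each), a log2 fold change of 1.70 with a standard error of 0.16 and an adjusted p of 0.0464 in edgeR's quasi-likelihood test. It was higher in each of the 3 Girk3-null libraries than in any wild type library. Car8 was the only gene of 17554 tested that passed an adjusted p of 0.05, so 1 gene was higher and 0 were lower. At an unadjusted p under 0.05 there were 2548 genes, 1315 higher and 1233 lower, where chance would give 878. Setting wild type replicates 1 and 2 and Girk3-null replicate 2 against the other 3 libraries gave 2732, more than the genotypes, and the other 8 splits gave 111 to 1606. The groups did not overlap for 3516 of the 17554 tested genes, where chance gives 10%. DESeq2 called 339 genes (181 higher and 158 lower) and limma-voom called 0. Without Girk3-null replicate 1 edgeR called 0 genes, and Car8 then had a log2 fold change of 1.68 with an adjusted p of 0.0994 (2.61e-19 to 0.366 over all 18 alternative settings, the lowest in DESeq2). Leaving out wild type replicate 1 or 2 or Girk3-null replicate 2 or 3 also ended the Car8 call. So did a covariate for title numbers below or above 200 (adjusted p = 0.215 in edgeR), library size only (0.0786), limma-voom (0.0575), and log2(RPKM + 0.1) and log2(RPKM + 1) in limma (0.303 and 0.253). Without wild type replicate 1 the 1 gene that passed was Ifi202b, named after its values were seen (log2 fold change 7.73, adjusted p = 0.00101), and without wild type replicate 3 edgeR called 74 genes.

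The 16 genes named next had the smallest p-values among genes with a mean log2 CPM of at least 1, 8 in each direction, and did not pass the edgeR test. Pydc4 and Gm4955, given below with the genes near Kcnj9, had smaller p-values than any of the 8 lower genes at a mean log2 CPM below 1 (adjusted p = 0.200 and 0.291 in edgeR). Among those higher in Girk3-null libraries were Alpl, the tissue-nonspecific alkaline phosphatase of mineralising cartilage and bone, and Pth1r, the receptor for parathyroid hormone-related protein. Alpl measured 81.0 ± 16.5 against 29.1 ± 3.64 CPM (log2 fold change 1.48, standard error 0.17, adjusted p = 0.129). Pth1r measured 100.3 ± 22.3 against 39.7 ± 9.84 CPM (log2 fold change 1.34, standard error 0.22, adjusted p = 0.291). Adjusted p was 0.291 in edgeR for the 14 others as well. The higher ones were Frzb, a secreted Wnt antagonist (log2 fold change 1.81), Chrdl1, a secreted BMP antagonist (2.15), Islr (0.91), Matn4, a cartilage matrilin (0.65), Omd (1.06) and Apoe (1.19). The lower ones were Slamf7 (-1.30), Pyhin1 (-2.19), Icos (-1.25), Cenpf (-0.92), Top2a (-1.11), Fam83d (-1.12), Calcrl (-1.08) and Tnnc2 (-2.45). All 16 genes had groups that did not overlap, and DESeq2 called all 16. Neither is independent support, since the genes were picked by p-value on the same counts. Slamf7 and Pyhin1 lie close to Kcnj9 on chromosome 1. Tnnc2, with 705 counts over all libraries, overlaps Ube2c on the opposite strand, with 2189 counts, and reads of the 2 genes cannot be told apart where counting ignores strand.

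**Figure D2:**
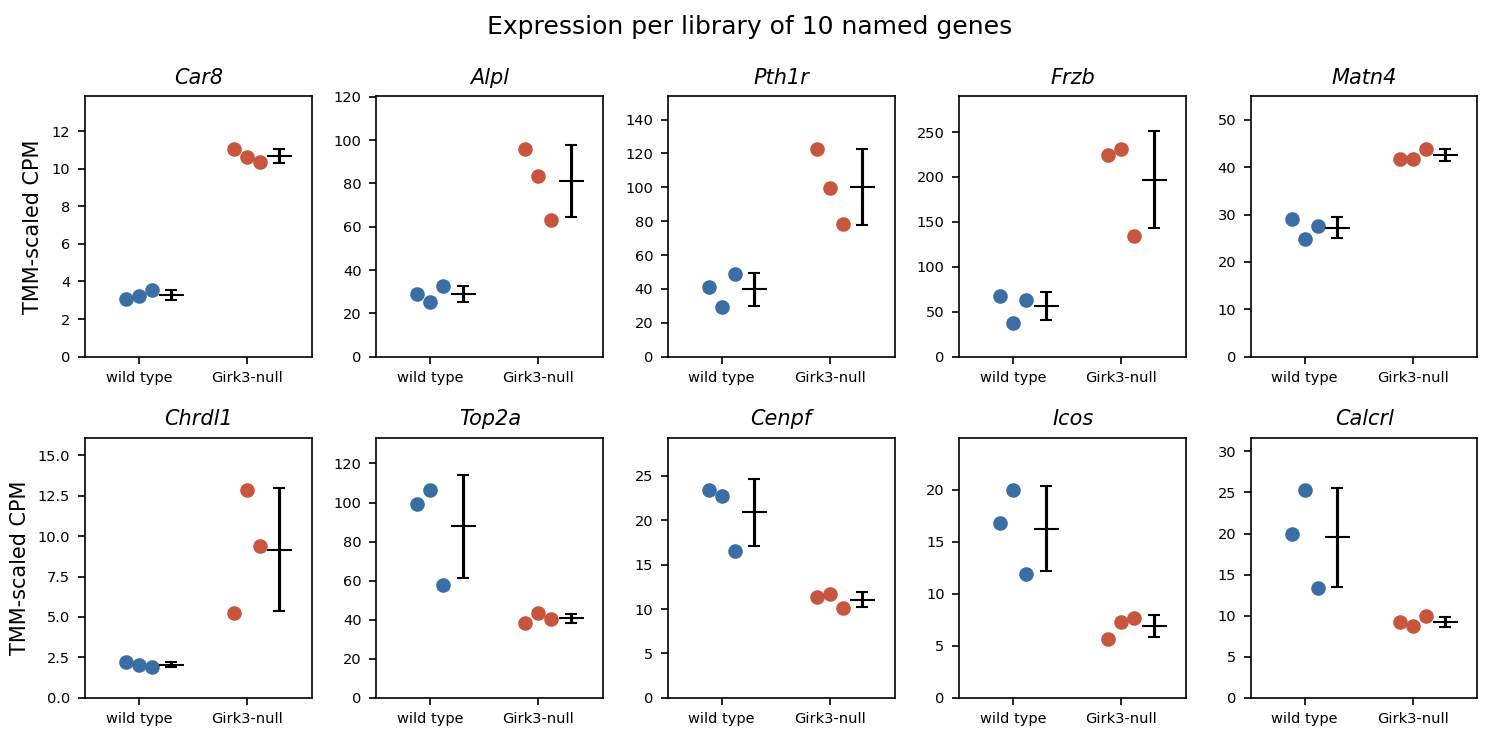
TMM-scaled CPM of 10 genes in each library (points), with the mean and SD of 3 libraries per group beside them. Car8 lies between 10.4 and 11.1 in Girk3-null and between 3.07 and 3.56 in wild type libraries; the other 9 genes did not pass the edgeR test.

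Genes of cartilage matrix and chondrocyte identity were higher in Girk3-null libraries. Of 30 list members 26 had a positive log2 fold change, with a median of 0.37, and 7 passed when adjusted over the list alone (all higher), while 0 passed over all genes tested. Matn4, Cnmd (listed as Lect1, a cartilage glycoprotein), Snorc (listed as 3110079O15Rik) and Col27a1 had the smallest p-values, with log2 fold changes of 0.65, 0.67, 1.06 and 0.85. Cnmd measured 830 ± 151 against 521 ± 14.9 CPM, and Col27a1 measured 1237 ± 63.8 against 688 ± 207 CPM. limma's camera with a preset correlation gave the list an adjusted p of 2.97e-05. With an estimated correlation, camera gave an adjusted p = 0.808. Col2a1 had a log2 fold change of 0.79 and did not pass over the list alone (adjusted p = 0.108 in edgeR). Without Girk3-null replicate 2 the median of the list was 0.20, with the title number covariate 0.23, and on log2(RPKM + 1) 0.24. Endothelial (-1.19), skeletal muscle (-0.97) and erythroid (-1.12) markers had negative medians in the same comparison.

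Hypertrophic chondrocyte genes, those of cells that enlarge and prepare for mineralisation, were also higher. Of 24 members 17 were positive with a median of 0.35, and 9 passed when adjusted over the list alone (8 higher and 1 lower). These included Alpl, Pth1r, Phospho1 (0.98) and Dlx5 (0.88). Phospho1, a phosphatase of matrix mineralisation, measured 53.2 ± 17.4 against 27.0 ± 2.84 CPM. Col10a1, the collagen that defines the hypertrophic zone, had a log2 fold change of -0.29 with a standard error of 0.39. The camera test gave an adjusted p of 0.00586 with the preset correlation. With an estimated correlation it gave an adjusted p = 0.808. Without wild type replicate 2 the median was 0.23, and on log2(RPKM + 0.1) and log2(RPKM + 1) it was 0.19 and 0.18. In the same comparison the median was -1.19 for endothelial, -0.97 for skeletal muscle and -1.12 for erythroid markers.

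The osteoblast and osteocyte list had a median of 0.55 with 15 of 20 members positive, and 7 passed when adjusted over the list alone (5 higher and 2 lower). Omd, Smpd3 (2.11) and Ibsp (0.77) were higher and Dmp1, an osteocyte matrix protein, was lower (-1.43). The preset camera test gave an adjusted p of 0.00988. The estimated correlation gave an adjusted p = 0.808. Without wild type replicate 3 the preset call ended as well (adjusted p = 0.0634, median 0.60). On log2(RPKM + 0.1) and log2(RPKM + 1) the median was 0.37 and 0.25. Ibsp, Spp1 and Sp7 stand in both the hypertrophic and the osteoblast list. As beside the hypertrophic list, endothelial (-1.19), skeletal muscle (-0.97) and erythroid (-1.12) markers had negative medians.

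Cell cycle genes were lower in Girk3-null libraries. All 32 members had a negative log2 fold change, with a median of -0.60, and 19 passed when adjusted over the list alone, against 0 over all genes tested. Top2a, a topoisomerase of dividing cells, measured 40.7 ± 2.45 against 87.8 ± 26.3 CPM. Cenpf, Cenpe and Ccnb1 had log2 fold changes of -0.92, -0.88 and -1.13. The preset camera test gave an adjusted p of 2.11e-15. With the estimated correlation the adjusted p = 0.808. The mean log2 CPM of the list was 4.48, 4.55 and 3.94 in wild type replicates 1, 2 and 3 and 3.56 to 3.77 in the Girk3-null libraries. Endothelial markers were lower in each Girk3-null library than in any wild type library, and erythroid and skeletal muscle markers had negative medians with groups that overlapped, as given below.

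ERK pathway targets, genes induced by mitogen-activated kinase signalling, had a median of -0.30 with 16 of 20 members negative. Over the list alone 3 passed, Spry4 (-0.40), Il1rl1 (-0.88) and Dusp6 (-0.39), and Spry1 (-0.86) did not. The preset camera test gave an adjusted p of 0.00374. With the estimated correlation the adjusted p = 0.808, and without Girk3-null replicate 1 the preset adjusted p = 0.0701 with a median of -0.13. The list averaged 5.67, 5.72 and 5.66 log2 CPM in wild type replicates 1, 2 and 3. It averaged 5.17, 5.42 and 5.67 in Girk3-null replicates 1, 2 and 3, so the groups overlapped. Endothelial markers were also lowest in Girk3-null replicate 1, at 1.20 log2 CPM. Interferon response genes had a median of -0.67 with 22 of 24 negative and 0 passing over the list alone. The 4 members with the smallest p-values, Oasl2, Ifit2, Rsad2 and Gbp2, had log2 fold changes of -1.08, -0.90, -1.28 and -0.74. The preset camera test gave an adjusted p of 0.00943. With the estimated correlation the adjusted p = 0.855. This list stood highest in wild type replicate 1 (mean log2 CPM 4.79, against 4.17 and 3.07 in replicates 2 and 3 and 2.98, 4.06 and 3.34 in the Girk3-null libraries). Erythroid markers (median -1.12) were likewise highest in wild type replicates 1 and 2 and Girk3-null replicate 2. Without wild type replicate 1 the interferon median was -0.21 with an adjusted p of 0.654 in the preset camera test. The same test gave 0.142 without Girk3-null replicate 1 (median -0.44) and 0.0760 without Girk3-null replicate 3 (median -0.43), and the median was -1.07 without Girk3-null replicate 2 and -0.30 with the title number covariate.

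Markers of other cell types that a collagenase digest can carry were lower for 3 types. Endothelial markers had a median of -1.19 with 14 of 16 negative and 8 passing over the list alone, including Cldn5 (-2.23), Egfl7 (-1.05), Tek (-1.45) and Kdr (-1.55). Kdr measured 5.05 ± 2.75 against 14.6 ± 6.41 CPM. Skeletal muscle markers had a median of -0.97 with 16 of 20 negative and 6 passing over the list alone, among them Tnnc2, Myl1 (-2.11), Mylpf (-1.35) and Myh8 (-2.66). Erythroid markers had a median of -1.12 with 12 of 12 negative and 0 passing over the list alone; Epb42 (listed as Epb4.2), Kel and Hbb-bt had log2 fold changes of -1.43, -1.50 and -1.22. The preset camera test gave adjusted p-values of 9.05e-06, 0.00012 and 0.00266 for the 3 lists in that order. With the estimated correlation each had an adjusted p = 0.808. The erythroid list averaged 2.35 and 2.77 log2 CPM in wild type replicates 1 and 2 and 0.73 in wild type replicate 3, against 0.27, 1.94 and 0.49 in the Girk3-null libraries. Without Girk3-null replicate 1 its median was -0.68 with an adjusted p of 0.0543 in the preset camera test, and it was -0.67 without wild type replicate 2, -1.87 without Girk3-null replicate 2 and -0.61 on log2(RPKM + 1). Endothelial markers averaged 1.20 log2 CPM in Girk3-null replicate 1, 2.69 and 2.84 in Girk3-null replicates 2 and 3, and 3.15 to 3.73 in the wild type libraries. Skeletal muscle markers averaged 1.88, 1.79 and 0.45 log2 CPM in the wild type libraries and 1.13, -0.63 and 0.23 in the Girk3-null libraries, so the groups overlapped. Without Girk3-null replicate 1 the median was -0.70 for endothelial and -1.79 for skeletal muscle markers, and both lists passed the preset camera test. The skeletal muscle median was -0.53 with the title number covariate and -0.31 on log2(RPKM + 1).

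**Figure D3:**
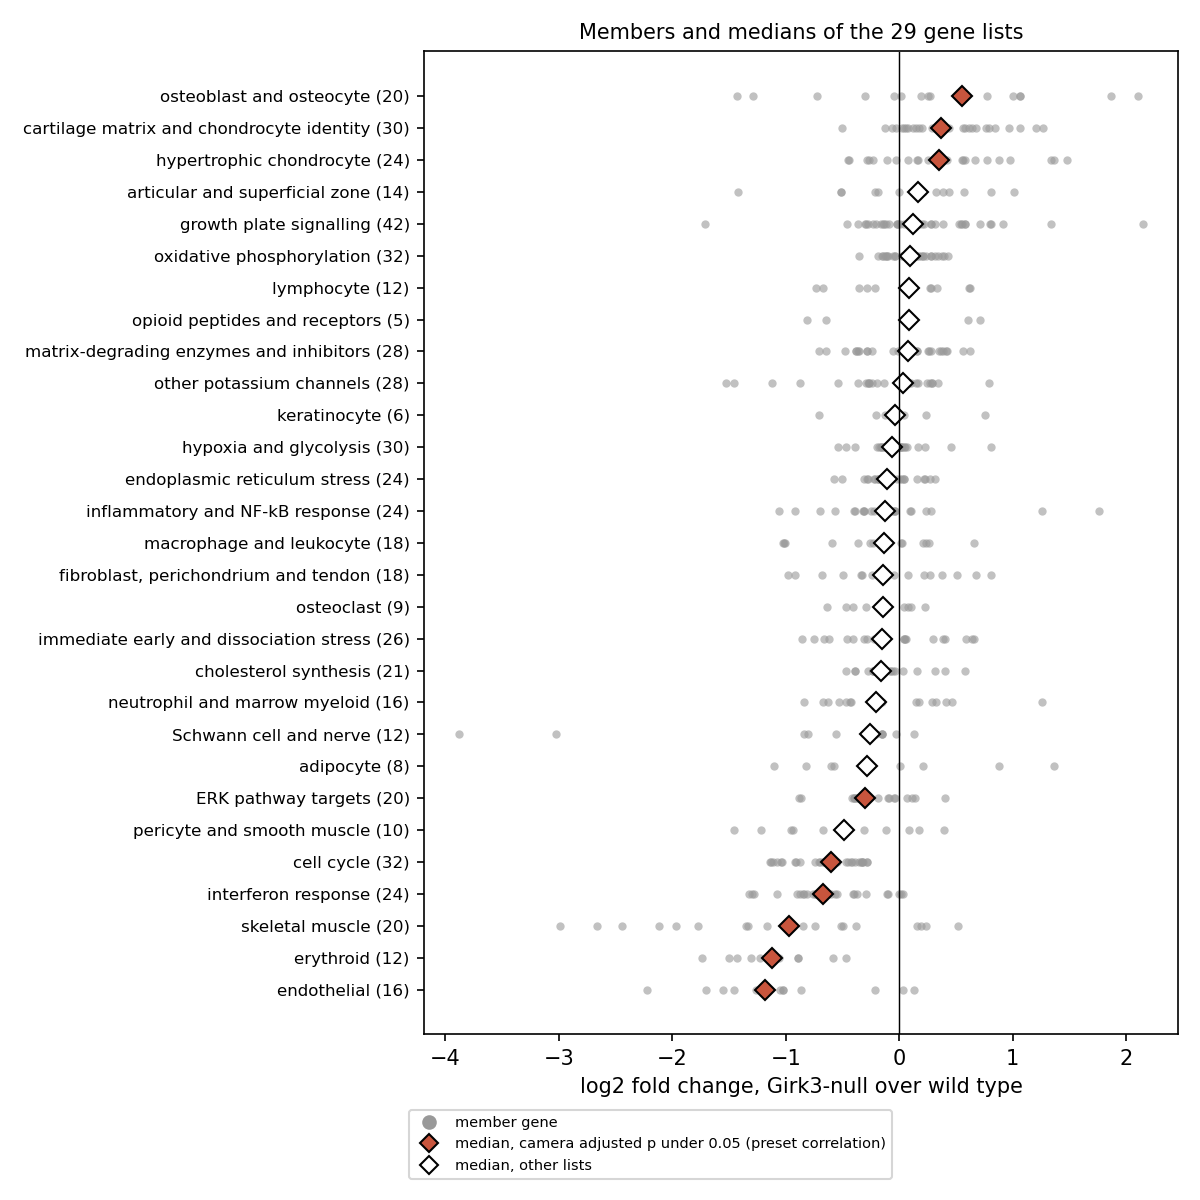
Log2 fold change (Girk3-null over wild type, n = 3 each) of every tested member (grey points) and the median (diamonds) of 29 gene lists, with the number of tested members in brackets. The 3 filled medians at the top are 0.55, 0.37 and 0.35 and the 6 filled ones below 0 run from -0.30 to -1.19; 0 lists passed with an estimated correlation.

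In all, 9 of 29 lists passed the camera test with the preset correlation (3 higher and 6 lower). With the estimated correlation 0 passed, and 0 passed with fry. Estimates were 0.93 for the erythroid list, 0.86 for interferon, 0.70 for cell cycle and endothelial, and 0.51 for skeletal muscle. They were 0.30 for cartilage, 0.23 for ERK targets, 0.12 for hypertrophic and -0.00042 for osteoblast lists, against the preset of 0.01. Where genes correlate more than the preset, its p-values are too small. In the other 9 splits of the 6 libraries into 3 and 3 it called 5 to 13 lists. Without Girk3-null replicate 1 the preset test called 7 lists, 6 of them among the 9. Medians were then 0.45 for cartilage, 0.25 for hypertrophic, 0.37 for osteoblast and -0.53 for cell cycle genes.

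The 20 other lists did not pass. Opioid peptides and receptors, studied here because opioid receptors open these channels, had 5 tested members and a median of 0.08. Penk, the enkephalin precursor, measured 184 ± 70.6 against 288 ± 70.7 CPM (log2 fold change -0.65, adjusted p = 0.354 in edgeR). Oprd1, Oprl1 and Pomc lay between 0.159 and 0.456 CPM, with log2 fold changes of -0.81, 0.71 and 0.61. Oprk1 and Oprm1 had 0 counts in every library, and Pdyn, the dynorphin precursor, had 8 counts in Girk3-null replicate 1 and 0 in the other 5. The 28 other potassium channel genes had a median of 0.03, with Kcnj8 (-1.46), Kcnj2 (-1.12), Kcnj15 (0.79) and Kcne3 (-1.52) at the smallest p-values. Growth plate signalling genes had a median of 0.12 (adjusted p = 0.102 in camera), and 4 passed over the list alone. These were Chrdl1, Pth1r and Wnt5b (0.81), all higher, and Npr3, the clearance receptor for natriuretic peptides (-1.71).

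Medians of the remaining pathway lists were small. They were 0.16 for articular and superficial zone genes, where Vit (1.01), Gas1 (0.44) and Aspn (-1.42) passed over the list alone and Tnc (-0.51) did not. They were 0.08 for matrix-degrading enzymes and inhibitors (Adamts1 -0.64, Timp1 -0.36, Htra1 0.42, Mmp15 -0.71), -0.16 for immediate early and dissociation stress genes (Hsp90aa1 -0.66, Klf6 -0.40, Hspa1a -0.86, Jund 0.59) and -0.06 for hypoxia and glycolysis (Car12 0.81, Pfkfb3 0.45, Slc2a3 -0.39, Ankrd37 -0.54). Oxidative phosphorylation had 0.09 (Ndufa2 0.43, Ndufa1 0.40, Uqcrq 0.32, Ndufc1 0.38), endoplasmic reticulum stress -0.11 (Dnajb9 -0.57, Calr 0.32, Asns -0.51, Syvn1 0.23) and cholesterol synthesis -0.16 (Mvk 0.58, Srebf2 0.32, Idi1 -0.47). The inflammatory and NF-kB list had -0.13, with 18 of 24 members negative. Its acute-phase genes Saa3 (1.76) and Lcn2 (1.26) were higher over the list alone, and Il6 (-0.57) and Vcam1 (-1.06) did not pass. Lcn2 measured 1976 ± 675 against 825 ± 288 CPM.

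Medians of the remaining cell type lists were -0.26 for Schwann cell and nerve (adjusted p = 0.0597 in camera; Pmp2 -3.88, Mbp -0.84, Prx -0.56), -0.49 for pericyte and smooth muscle (Kcnj8, Rgs5 -0.96, Abcc9 -1.22, Mylk 0.39) and -0.13 for macrophage and leukocyte (C1qb -1.02, C1qc -1.03, Mrc1 -0.59, Cd68 0.66). They were -0.15 for osteoclast (Itgb3 -0.41, Atp6v0d2 -0.47, Acp5 0.22, Dcstamp -0.63), -0.28 for adipocyte (Plin4 0.88, Cd36 -0.82, Pparg -0.58, Fabp4 -0.60) and -0.14 for fibroblast, perichondrium and tendon (Cd34 -0.98, Tnmd -0.92, Pdgfra -0.32, Col5a1 0.37). Keratinocyte markers had -0.04 (Perp -0.71, Trp63 0.76, Sfn -0.20, Krtdap 0.24), lymphocyte markers 0.09 (Il7r -0.28, Ighm 0.61, Rag1 -0.73, Igll1 -0.67) and neutrophil and marrow myeloid markers -0.20 (Lcn2, Fcnb -0.84, Mpo 0.41, Ngp -0.62). The median and the camera direction had opposite signs for the lymphocyte, opioid, other potassium channel and matrix-degrading enzyme lists.

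Of these 20 lists, 10 passed the preset camera test in at least 1 alternative setting, growth plate signalling and oxidative phosphorylation higher and the other 8 lower. Without wild type replicate 3 they were Schwann cell and nerve (adjusted p = 0.00196), macrophage and leukocyte and pericyte and smooth muscle (0.0180 each) and cholesterol synthesis (0.0203). Without wild type replicate 2 they were oxidative phosphorylation (0.0236) and immediate early and dissociation stress (0.0397), and without Girk3-null replicate 1 growth plate signalling (0.0323). Without Girk3-null replicate 2 they were macrophage and leukocyte and lymphocyte (0.0272 each), and growth plate signalling, immediate early and dissociation stress, neutrophil and marrow myeloid, and Schwann cell and nerve (0.0482 each). Without Girk3-null replicate 3 they were immediate early and dissociation stress (0.00051), oxidative phosphorylation (0.00734), inflammatory and NF-kB (0.0274), pericyte and smooth muscle (0.0355) and Schwann cell and nerve (0.0361). With the title number covariate they were immediate early and dissociation stress (0.00406) and oxidative phosphorylation (0.00895), and at an adjusted p under 0.1 Schwann cell and nerve.

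Genes close to Kcnj9 were examined because a deletion made in stem cells of another mouse strain can carry neighbouring sequence of that strain. Of 214 tested genes within 10 Mb of Kcnj9, 0 passed the adjusted threshold, against 1 of 17340 elsewhere. At an unadjusted p under 0.001, a threshold chosen after the data were seen, 7 of 214 (3.27%) lay within 10 Mb and 32 of 17340 (0.185%) elsewhere, an odds ratio of 18.3 (two-sided Fisher's exact test, p = 4.01e-07). That test takes genes as independent, and 4 of the 7 are neighbours of 1 gene family. DESeq2 called all 7, of which 6 are named here. Picked by p-value on the same counts, they gain no independent support from that. At an unadjusted p under 0.05, a threshold also chosen after the data were seen, the shares were 17.3% and 14.5% (p = 0.242, the same exact test). Within 5 Mb they were 25% and 14.4% (p = 0.0029, the same exact test). Pydc4 had 36, 81 and 28 counts in the wild type libraries and 2, 1 and 0 in the Girk3-null libraries, Gm4955 had 58, 100 and 39 against 2, 6 and 0, and Pydc3 had 92, 79 and 20 against 6, 6 and 8. Pyhin1, of the same gene family, had 213, 314 and 113 counts against 38, 54 and 32. These are related interferon-inducible genes, and reads of close copies cannot be told apart in gene counts. Slamf7 had 195, 232 and 157 counts against 88, 82 and 51. Atp1a4, a sodium pump subunit gene 97.0 kb from Kcnj9, had 16, 7 and 17 counts against 299, 62 and 84.

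**Figure D4:**
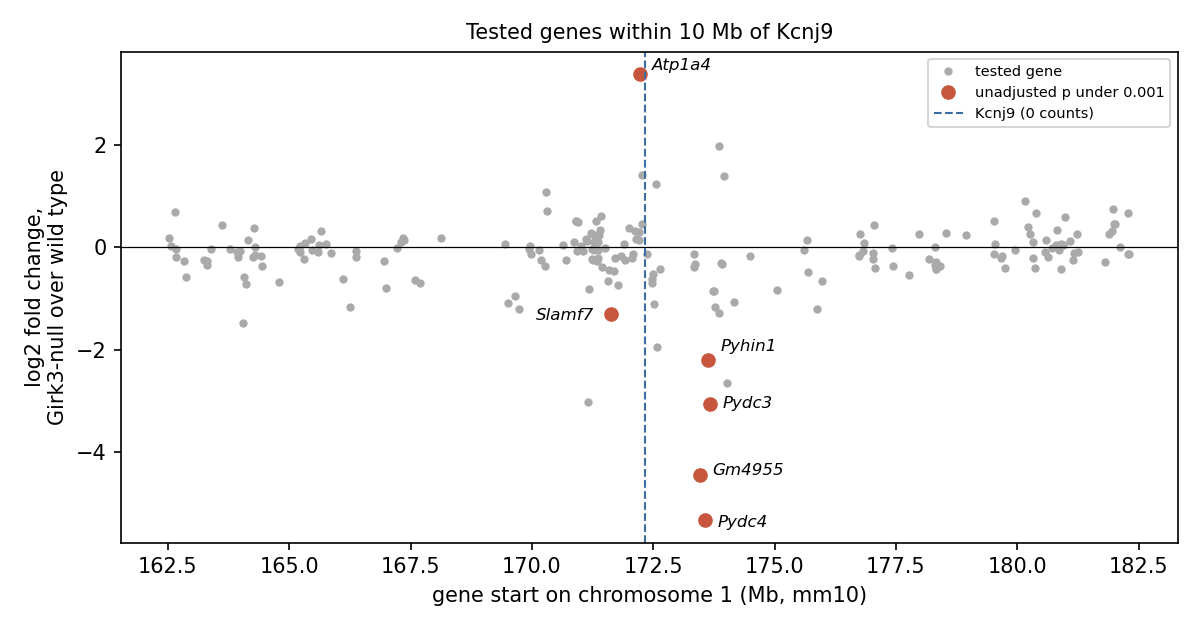
Log2 fold change (Girk3-null over wild type) of 214 tested genes by start position on chromosome 1 (Mb, mm10), within 10 Mb of Kcnj9 (dashed line), with 1 of them not drawn. The 6 genes drawn in red with their names have an unadjusted p under 0.001, and 5 of them are lower in Girk3-null libraries.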

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

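Tests chosen only after the results were seen were those of genes near Kcnj9 at an unadjusted p under 0.001, as that threshold was chosen then, the Ifi202b count, the Xist share, and the tests of the 9 lists for sex, for chondrocyte share and for other cells.

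Y-linked transcripts stood out because the genotype comparison does not use them and they were at 0 in every wild type library. Girk3-null replicate 1 had 16088 counts of Ddx3y, Eif2s3y, Kdm5d and Uty together, while all 6 libraries are labelled male. RNA of a male library mixed into a female one is argued against, since Xist in Girk3-null replicate 1 was 0.0140% of its mean in the other 5 libraries. That the other 5 come from females may account for the pattern, because all 4 genes tested that escape X inactivation (Kdm6a, Kdm5c, Eif2s3x and Ddx3x) were lowest in Girk3-null replicate 1, with Kdm6a at 41.9 CPM there and 86.0 ± 8.07 CPM (mean ± SD) in the other 5. A wrong sex label and an exchange with samples outside the series both stay open, and Kcnj9 at 0 counts everywhere left the genotype labels unchecked.

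The genes close to Kcnj9 form a pattern of 7 genes at an unadjusted p under 0.001, within 10 Mb, and the highest number in any of the other 9 splits of the 6 libraries into 3 and 3 was 3, with 1 of 10 splits reaching 7 (10 splits are too few for a share under 0.05). Windows of the same size elsewhere held at most 3 such genes. This cannot decide whether neighbouring genes moved together, as they may anywhere in the genome. Of the 7 genes, 4 are neighbours of 1 gene family, and the test counted each of them alone. The interferon level of the libraries is only weakly argued against as the whole cause. The median absolute log2 fold change of the 7 genes was 3.05 without and 2.31 with the interferon list mean as a covariate. So 75.7% was kept, only just over the bound set for this test. All 7 stayed over 2 standard errors, but they had been picked by p-value in the same libraries. A local difference at the deleted locus stays open as untested, either sequence of another strain beside the deletion, which can also change how reads align, or an effect of the deletion on its neighbours. Ifi202b, 1.64 Mb from Kcnj9, had 1236 counts in wild type replicate 1 and 4 and 6 in wild type replicates 2 and 3. It had 1035, 1204 and 771 in the Girk3-null libraries. High Ifi202b counts were therefore not particular to the Girk3-null libraries. The test was chosen after these counts were seen. It cannot decide on a stretch of other sequence that wild type replicate 1 carries too.

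The 9 gene lists that passed the preset camera test form the other pattern weighed. The real split called 9 lists and the highest of the other 9 splits called 13, with 6 of 10 splits calling at least 9, and 10 splits are too few for a share under 0.05. Without Girk3-null replicate 1, 6 of the 9 were called in the same direction, but erythroid, interferon and ERK target genes were not. For those 6 this argues only weakly against the sex of that library as the cause. The preset test also called 5 to 13 lists in the other splits, so a call that stays is little evidence. A larger share of chondrocytes that moves all cartilage genes by 1 factor is argued against, since 14 of the 30 cartilage list members lay over 2 standard errors from the list's median (7 above and 7 below). That test covers a shift by 1 factor only, so a larger chondrocyte share that moves the list genes unequally stays open as untested. Fewer cells of all other types alike cannot be told apart from a loss of endothelial, erythroid and muscle cells alone, because that difference from leukocyte lists, with means of -1.27 and -0.33 on the log2 scale, was lower in each Girk3-null than in any wild type library but with a gap of 0.15 between the groups, under the larger SD of 0.52 (a bound set after the values were seen), and the deletion itself stays open as an untested cause.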

How the results depend on the processing

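The count of changed genes depended on the tool, the filter and the libraries. DESeq2 called 339 genes (181 higher and 158 lower), and no low-count filter gave 53 (35 higher and 18 lower). limma-voom, library size only, log2(RPKM + 0.1), log2(RPKM + 1), the title number covariate and an adjusted p under 0.01 each gave 0 genes changed and 0 higher. Leaving out each library gave 0 to 74 genes changed, 0 to 28 higher and 0 to 46 lower, with 74 reached without wild type replicate 3, of which 50 were also DESeq2 calls. The cause was not tested. Car8 kept its direction in all 18 settings (log2 fold change 0.96 to 1.77) and passed in 7, with an adjusted p of up to 0.366 in edgeR, limma or DESeq2. The list count was 0 with the estimated correlation and 0 with fry, and 7 to 15 with each library left out, 15 without Girk3-null replicate 2. The interferon list did not pass with library size only, either RPKM scale or the title number covariate (adjusted p of 0.0575 to 0.0996 in camera), nor the erythroid list with log2(RPKM + 1) (adjusted p = 0.0538 in camera). The list count was 5 of 16 without genes of other cell types, an alternative chosen after seeing the data, which tests fewer lists. Near Kcnj9, unadjusted thresholds chosen after seeing the data gave 28 genes within 5 Mb at p under 0.05, and 7 within 5 Mb, 7 within 10 Mb and 8 within 20 Mb at p under 0.001. Of 2794 values of single lists and genes under alternatives, 2599 kept direction and side of the threshold, 40 kept direction and no longer passed, 106 kept direction and newly passed, and 49 (40 of lists and 9 of genes) changed sign. Of these 49, 48 passed in neither setting, and 1, the lymphocyte list without Girk3-null replicate 2, newly passed; the cause was not tested. The lists that changed sign had these medians: other potassium channels -0.13 with limma-voom, -0.085 with library size only, -0.14 with no low-count filter, -0.090 with log2(RPKM + 0.1), -0.032 with log2(RPKM + 1) and -0.10 with the covariate; lymphocyte -0.11, -0.035, -0.11, -0.010 and -0.038 in the same settings other than no low-count filter. Library size only, log2(RPKM + 0.1) and log2(RPKM + 1) gave opioid -0.029, -0.012 and -0.012, matrix-degrading enzymes -0.034, -0.033 and -0.028, and oxidative phosphorylation -0.014, -0.019 and -0.018. Adipocyte had 0.0055 with no low-count filter, osteoclast 0.044 with at least 1 CPM in 3 libraries, and neutrophil 0.025 with the covariate. Krtdap had -0.10 with limma-voom, -0.078 with log2(RPKM + 0.1) and -0.33 with the covariate. With each library left out, medians ran from -0.27 to 0.025 for other potassium channels, -0.43 to 0.43 for lymphocyte, -0.81 to 0.20 for neutrophil, -0.35 to 0.019 for macrophage, -0.22 to 0.17 for keratinocyte, -0.057 to 0.14 for matrix-degrading enzymes, -0.32 to 0.10 for immediate early, -0.10 to 0.013 for hypoxia and -0.39 to 0.021 for adipocyte genes. Log2 fold changes then ran from -0.23 to 1.08 for Ighm, -0.17 to 0.67 for Kcnj5, -0.17 to 0.67 for Krtdap, -1.48 to 0.032 for Rag1 and -0.59 to 0.17 for Sfn. Library size only moved the median of all genes to -0.09. Kcnj9 had no counts, so no setting gave it a fold change. No paired analysis was possible because the labels give no shared replicate numbers. The real split called 1 gene and the highest of the other splits called 5, with 2 of 10 splits calling at least 1. The split with 5 sets wild type replicates 1 and 2 and Girk3-null replicate 2 against the rest, and 10 splits are too few for a share under 0.05. Depth limits statements on Kcnj9, Oprk1 and Oprm1, whose 0 counts allow up to 0.0875 CPM.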

Other observations

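Except for C1qb and C1qc, the genes in the first 3 paragraphs were chosen after their values were seen, and none passed edgeR's adjusted threshold in the comparison of all 6 libraries. The complement genes C4b, C1s1, C1ra and Cfb were higher in each Girk3-null library than in any wild type library, and the complement genes C1qb and C1qc were lower in each (log2 fold changes -1.02 and -1.03). C4b measured 473 ± 86.5 against 264 ± 49.2 CPM, C1s1 108 ± 16.5 against 64.4 ± 6.26 CPM, C1ra 66.4 ± 10.8 against 35.9 ± 6.82 CPM and Cfb 372 ± 138 against 155 ± 39.9 CPM (Girk3-null against wild type, mean ± SD, n = 3 each). The log2 fold changes of these 4 were 0.84, 0.74, 0.89 and 1.26. No list of complement genes was tested.

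Fzd2, Fzd8 and Fzd9, which encode Wnt receptors, had log2 fold changes of 0.73, 0.76 and 0.75, and Wnt4, which encodes a Wnt ligand, had 1.65. No other Fzd gene was among the 339 genes called by DESeq2, so the named ones do not stand for the family. No list of Wnt signalling genes was tested. Wnt4 measured 11.2 ± 5.78 CPM in Girk3-null and 3.60 ± 0.30 CPM in wild type libraries.

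Ifi202b, an interferon-inducible gene (chromosome 1, 173962568 to 173982744, mm10), was read in 4 libraries with 771 to 1236 counts and stayed at 4 and 6 counts in wild type replicates 2 and 3. Of the genes that reach 2 CPM in some library, 10 have a gap of at least 10-fold between neighbouring values when the 6 libraries are sorted. Of these, 8 lie on chromosome X or Y, and Ifi202b is among the 2 on autosomes. Wild type replicate 1 thus stood with the Girk3-null libraries in Ifi202b and with wild type in Pydc4, where it had 36 counts.

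The first principal component of log2 CPM held 42.6% of the variance. Wild type replicates 1 and 2 had scores of -38.5 and -44.3, wild type replicate 3 had 7.12, and the Girk3-null libraries had 54.9, 4.85 and 15.9. Across genes, wild type replicates 1 and 2 had the highest correlation of any pair (Pearson's r = 0.992); genes are not independent replicates. The title numbers fall below 200 in wild type replicates 1 and 2 and Girk3-null replicate 1, which did not lie together on that component, and above 200 in wild type replicate 3 and Girk3-null replicates 2 and 3, which had the 3 scores from 4.85 to 15.9. Wild type replicate 3 had a Pearson's r of 0.986 with each of these 2 Girk3-null libraries and 0.982 and 0.981 with wild type replicates 1 and 2.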
